A study of Rattus norvegicus with 9 samples.

How the data were processed

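Whole-transcript Affymetrix arrays were made from RNA of laser-microdissected rat liver, 9 arrays in all. Per the labels' protocols, female F344 rats received 2 injections of retrorsine at 30 mg/kg, 2 weeks apart, and a partial hepatectomy 4 weeks after the second. Frozen sections of 7 µm were stained with hematoxylin, and SHPC clusters or hepatocytes next to them were captured. RNA was extracted with RNeasy Mini columns and labelled with Ambion's whole-transcript kit. Donor cells entered through the spleen, and the number of cells is not printed here because its exponent is unclear in the label. Groups were taken from the cell type and treatment labels. For the hepatocyte group the description label speaks of SHPCs with transplantation, while the cell type label and the titles give hepatocytes as controls; the cell type label was followed. The number of animals and which regions share one were not given in the sources used here, so no animal could enter a fit.

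The deposited table holds an intensity on the linear scale for 36685 probe sets on each array. The values were made with RMA, which corrects background, normalizes between arrays and summarises probes to probe sets, per the submitters' processing notes; its version and settings were not given in the sources used here. RMA usually ends on a log2 scale, and the deposited values appear to have been taken back to the linear scale. No value was missing (0) and 0 columns belonged to other samples. The log2 of each value was taken here. The arrays' median intensity lay between 19.6 and 24.1 on the linear scale, and 0 pairs of arrays held identical values throughout. Single probe sets did: 337 were equal on all 3 SHPC arrays, 648 on all 3 SHPC arrays of transplanted livers and 319 on all 3 hepatocyte arrays, for reasons not given in the sources used here. Of tested genes these were 134, 325 and 133, which lowers their pooled variance, and 0 of them passed in a comparison of the group with equal values. The number of arrays, 3 per group, limits the precision.

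Probe sets were named from the platform annotation, which lists 19086 of them: 18511 with 1 gene symbol and 575 with several, which were not named. The other 17599 are unnamed here. Entrez IDs of 18394 were found in the RefSeq gene table of assembly GRCr8, and 0 symbols needed updating. No genome build was given in the sources used here, so no coordinates are printed. Of 18166 genes, 291 had more than 1 probe set, and the probe set with the highest mean over the 9 arrays stood for its gene. A gene was tested if at least 3 of the 9 arrays exceeded that array's 25th percentile over all probe sets, which left out 2373 genes as dim and kept 15793.

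Groups were compared with limma 3.58.1 in R 4.3.3, in a single fit of 3 group means over all 9 arrays (6 residual degrees of freedom) with eBayes and Benjamini-Hochberg adjustment at 0.05. A change is given on the log2 scale with limma's SE. The tests of the comparisons, the samples, gene lists, rule for named genes and alternatives other than the 2 named as later additions were chosen before the data were examined. Further tests chosen later are named at the top of the other observations. Changes of gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 34 lists within a comparison. Each list needed at least 5 tested members, and 610 of 721 list members were measured. Counts adjusted over the list alone apply Benjamini-Hochberg to the members' limma p-values. The lists hold mature hepatocyte, xenobiotic P450, pericentral, periportal, urea cycle, gluconeogenesis, fetal and progenitor hepatocyte, S phase, G2 and M phase, p53, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, bile acid, acute phase, complement, interferon, interleukin 17, growth factor, Hippo YAP, NRF2, unfolded protein response, glycolysis, oxidative phosphorylation and ribosomal protein genes. Lists of other cell types hold markers of cholangiocytes, endothelium, Kupffer cells, stellate cells, T and NK cells, B cells, neutrophils, erythroid cells and mesothelium. Some genes belong to several lists, such as Cps1, Ass1, Asl and Arg1 to the periportal and urea cycle lists and Cyp2e1 to the pericentral and P450 lists. Counts of shifted lists therefore do not count separate signals.

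Named genes followed a fixed rule of up to 30 per comparison. It took the 6 largest rises and 6 largest falls among genes past the threshold whose arrays lay apart, or, with fewer passing, those passing and then the smallest unadjusted p in that direction. It then took up to 2 members with the smallest p from each list in order of camera p. Il17rb, Il17ra, Il17b, Il25, Cxcr2, Thy1, Dpp4, Alb and Afp were always included. Other list members named as examples, and the members that passed adjusted over a list alone, were chosen after their values were seen. Genes known only by a numbered locus were not named.

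Equal replicate numbers in the labels were checked for pairing through the correlation, over genes, of deviations from the group means. Between SHPC and hepatocyte arrays of equal number it was 0.526, 0.705 and 0.341, all over 0.1, so these numbers were taken to pair the samples; the pairing comes from the data, since no label ties a number to an animal or day. For number 2 these are the arrays that stood apart from the others. SHPC array 3 correlated better with hepatocyte array 1 (0.480) than with hepatocyte array 3. Over numbers 1 and 3 alone the correlation was 0.0978, under 0.1, so the pairing rests on the number 2 arrays and is not established.

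Each fit was tested on simulated data with 5 sets of 200 changed genes among 15793. The noise of these sets was drawn independently for each gene and array from the gene's pooled SD. It held no correlation between genes and no arrays or groups of unlike spread, so the rates below may not hold for the real arrays. Genes changed 4-fold were recovered in 94.0%, 95.6% and 96.0% of cases for SHPCs with against without transplantation, SHPCs against hepatocytes, and SHPCs of transplanted livers against hepatocytes, and genes changed 2-fold in 60.8%, 58.4% and 60.4%, with 10.2, 8.2 and 10.6 false calls per set. In 100 draws of unchanged groups with the arrays' own correlation between genes, a median of 0 genes was called, while camera at the preset correlation called a median of 8, 9.5 and 7 lists (95th percentile 18.1, 18 and 17.1). With an estimated correlation it called 0 in every draw. Every array of these draws mixed the deviations of all real arrays, so no group had a wider or narrower spread by design. The real groups differed in spread, so these counts may understate calls of unchanged genes or lists in SHPCs against hepatocytes.

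Alternatives were other filters on dim genes, renewed quantile normalization, median centring, cyclic loess, other probe set rules, eBayes with trend and robust settings, array quality weights, fits of the compared groups alone, the replicate number as a fixed or random block, other thresholds, other list tests and each array left out in turn. Figures were drawn with matplotlib 3.10.9 from tables handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. Random draws used seed 1.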

Results

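Gene expression was measured on whole-transcript Affymetrix arrays in rat liver regrowing after retrorsine and partial hepatectomy. Retrorsine is a plant alkaloid that keeps most hepatocytes from dividing, so that after removal of part of the liver the tissue regrows from clusters of small hepatocyte-like progenitor cells (SHPCs). Cells positive for Thy1, a surface protein, from rats with the enzyme dipeptidyl peptidase 4 (gene Dpp4) were given to some of the animals, which the labels describe as negative for that enzyme. The 9 arrays fell into 3 groups of 3 arrays: SHPC clusters of livers without transplantation, SHPC clusters of livers that received Thy1+ cells, and hepatocytes lying beside SHPC clusters in livers without transplantation. All material was taken by laser microdissection from frozen sections 7 µm thick, with clusters chosen by their look under the microscope. The number of animals behind the regions was not given in the sources used here, and the labels tie no region to an animal. The limma p-values below therefore rest on the spread between arrays, pooled over all 3 groups. On average, log2 values deviated from the group mean by at most 0.0993 on the transplanted group's arrays and at least 0.143 on the others. Camera at its preset correlation instead sets a list's gene statistics against those of other genes. In draws of unchanged groups, which gave every group the same spread by design, it called a median of 7 to 9.5 lists. Both kinds of p-value are too small if arrays of a group share an animal. The number of arrays limits the precision of every value.

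On the log2 scale, 15793 genes were tested. SHPC array 2 and hepatocyte array 2 stood apart from the other 7 arrays. Their median intensities were 24.1 and 23.0 on the linear scale against 19.6 to 20.6 for the others, and the SD of their log2 values was 1.94 and 1.98 against 2.09 to 2.13. They lay at 54.1 and 42.2 on the principal component that held 54.4% of the variance, where the other arrays lay between −22.8 and 2.30. None of the transplanted group's arrays was of that kind. No quality measure was analysed here, so a technical difference and a difference between animals cannot be told apart for these arrays. Among genes whose level marks the cell type, albumin (Alb) was at 13.61 ± 0.06, 13.63 ± 0.06 and 13.67 ± 0.02 in hepatocytes, SHPCs and SHPCs of transplanted livers (log2 intensity, mean ± SD, n = 3 each). That is near the top of the arrays' range, with maxima of 13306 to 14711 on the linear scale, so a difference in Alb may not show.

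**Figure D1:**
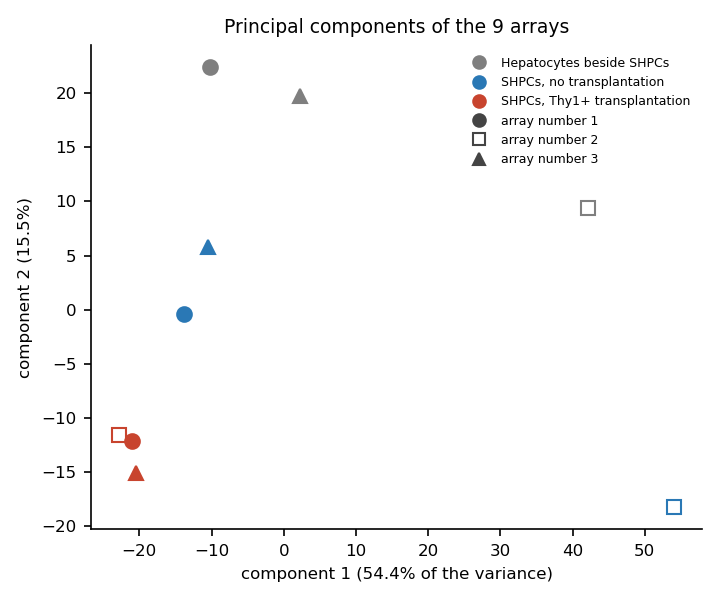
Principal components of the 9 arrays over 15793 genes, with component 1 (54.4% of the variance) on the horizontal axis and component 2 (15.5%) on the vertical axis. Each point is an array, colours give the group and shapes the array number, and SHPC array 2 (54.1) and hepatocyte array 2 (42.2) lie to the right of the other 7.

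The comparison of SHPC clusters with and without Thy1+ cell transplantation asks what the transplanted cells change in the progenitor clusters. Cyp2b1, a drug-metabolising cytochrome P450, was 11.2-fold lower in SHPCs of transplanted livers. In camera, the lists of fatty acid synthesis, cholesterol synthesis, G2 and M phase and interferon response genes were higher in those SHPCs, as were markers of Kupffer cells, the macrophages of the liver, and fatty acid oxidation genes were lower. With the correlation between genes estimated from the arrays 0 of these lists passed (adjusted p = 0.598 for each with an estimated correlation), and fry called 0. Without SHPC array 2 the G2 and M phase, interferon and Kupffer medians went from 0.62, 0.56 and 0.55 to 0.33, 0.30 and 0.20. By single genes the difference was small in number: 1 of 15793 genes passed at an adjusted p under 0.05 in limma, 0 higher and 1 lower.

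That gene was Cyp2b1 (probe set 17614487). Its log2 level was 8.62 ± 0.74 in SHPCs and 5.14 ± 0.43 in SHPCs of transplanted livers (mean ± SD, n = 3 each), a change of −3.48 ± 0.33 (SE, limma adjusted p = 0.0188), and each transplanted array lay below each SHPC array. Hepatocytes, at 10.37 ± 0.08, lay above both. The close relative Cyp2b2 differed by −0.65 ± 0.57 (SE, limma adjusted p = 0.747), and probes for such near-identical genes may each read some of the other's RNA. The named genes with the next smallest p in each direction had all 3 arrays of one group apart from the other group's but missed the threshold. Lower in SHPCs of transplanted livers were Cyp1a1 by a log2 change of −2.10 ± 0.26 (SE), and the carnitine transporter gene Slc22a5 by −1.45 ± 0.19. The same held for Cpt1a, which brings fatty acids into mitochondria, at −1.75 ± 0.23, Eci1, an enzyme of fatty acid oxidation, at −2.25 ± 0.31, and Cyp8b1, an enzyme of bile acid synthesis, at −2.26 ± 0.32. Their limma adjusted p-values lay between 0.0609 and 0.0804. Higher were Rgs16, a regulator of G protein signalling, at 1.58 ± 0.20 (adjusted p = 0.0609), and the stress-response gene Nupr1 at 1.49 ± 0.22 (adjusted p = 0.0933). At an adjusted p under 0.1 there were 9 genes, 2 higher and 7 lower, and at an unadjusted p under 0.05 there were 1161, 800 higher and 361 lower. The call of Cyp2b1 ended without Thy1 array 1, 2 or 3 (limma adjusted p = 0.0538, 0.241 and 0.143), without hepatocyte array 1 (0.0934) or 3 (0.105). It also ended after median centring (0.114), in a fit of the compared groups alone (0.305) and over all probe sets (0.0826). Its change stayed between −3.86 and −3.12 without any one array. The count was 24 (18 higher, 6 lower) without SHPC array 1, 2 without hepatocyte array 2 and 23 (8 higher, 15 lower) without both of the arrays that stood apart, and the split of 0 higher and 1 lower became 3 and 14 after renewed quantile normalization and 16 and 24 after cyclic loess.

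**Figure D2:**
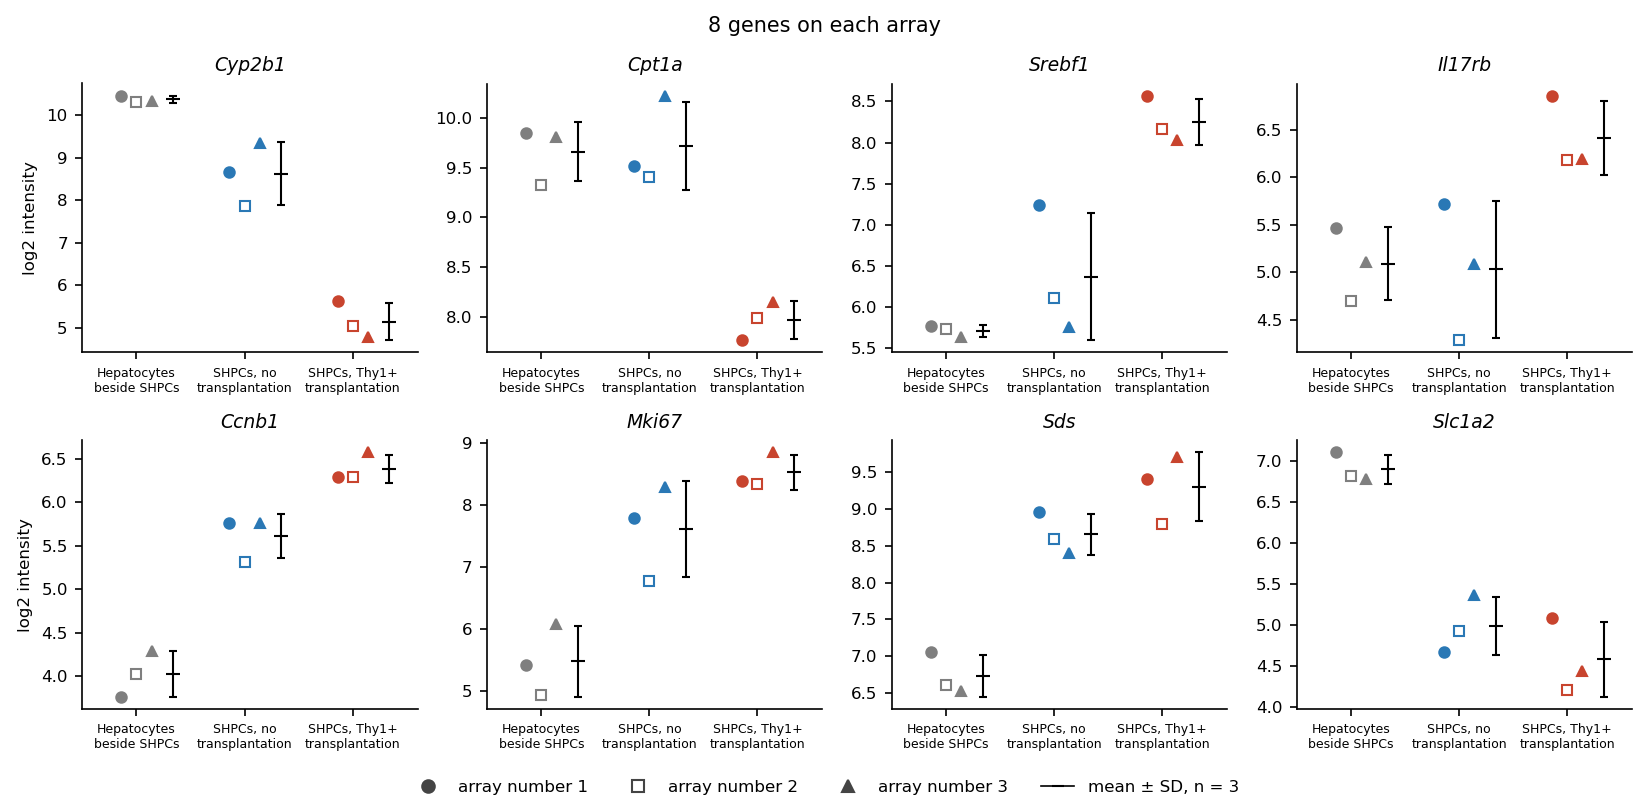
Log2 intensity of 8 genes on each of the 9 arrays, one panel per gene, with the groups on the horizontal axis. Points are arrays, and the bar beside each group is its mean ± SD (n = 3); for Cyp2b1 the group means are 10.37, 8.62 and 5.14 in hepatocytes, SHPCs and SHPCs of transplanted livers.

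Of the 34 gene lists tested with camera, 13 shifted between the SHPC groups, 11 higher and 2 lower in transplanted livers. With an estimated correlation 0 of the 34 passed (smallest adjusted p = 0.598), and 2 lists had an unadjusted p under 0.05. Fry, which called 0, tests the lists by themselves. Median centring of each array would add 0.103 to the median log2 change of all genes in this comparison, which was 0.02 as scaled by RMA, and the list medians below are to be read against that shift.

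All 14 measured fatty acid synthesis genes were higher in SHPCs of transplanted livers, with a median log2 change of 1.62, or 3.08-fold (camera adjusted p = 1.87e-14, adjusted p = 0.598 with an estimated correlation). In limma 12 of them passed adjusted over the list alone, against 0 over all genes tested. Examples were Srebf1, a transcription factor that switches on lipid synthesis, at 1.88 ± 0.32 (SE), the acetyl-CoA carboxylase genes Acaca and Acacb at 1.59 ± 0.33 and 1.54 ± 0.25, and the elongase gene Elovl6 at 3.15 ± 0.71. Of 17 cholesterol synthesis genes, 16 were higher, with a median of 0.97 (camera adjusted p = 1.80e-13, adjusted p = 0.598 with an estimated correlation). Here 13 passed adjusted over the list alone, again against 0 over all genes, among them Insig1 at 1.78 ± 0.40, Lss at 1.45 ± 0.34 and Sqle, the squalene epoxidase gene, at 1.12 ± 0.27. In the opposite direction, 19 of 20 fatty acid oxidation and PPAR alpha target genes were lower, with a median of −0.38 (camera adjusted p = 2.00e-08, adjusted p = 0.598 with an estimated correlation). Of these 5 passed adjusted over the list alone, against 0 over all genes, including Cpt1a, Acot1, Cyp4a1 at −1.08 ± 0.26 and the hormone gene Fgf21 at −0.95 ± 0.27. Acot1 had a mean of 2.69 on the log2 scale in transplanted livers, where the arrays' 25th percentiles over all probe sets were 2.85 to 2.89. On 1 of those arrays it lay at or below the percentile, so the size of its difference is not given. SHPC array 2, which stood apart, held the fatty acid synthesis list at −0.72 relative to the hepatocyte mean, against 1.03 and 0.11 for SHPC arrays 1 and 3. Without SHPC array 2 the medians were 1.25, 0.72 and −0.69, and the oxidation list's median was −0.24 without SHPC array 3 and −0.63 after cyclic loess, with all of these calls kept without each array.

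**Figure D3:**
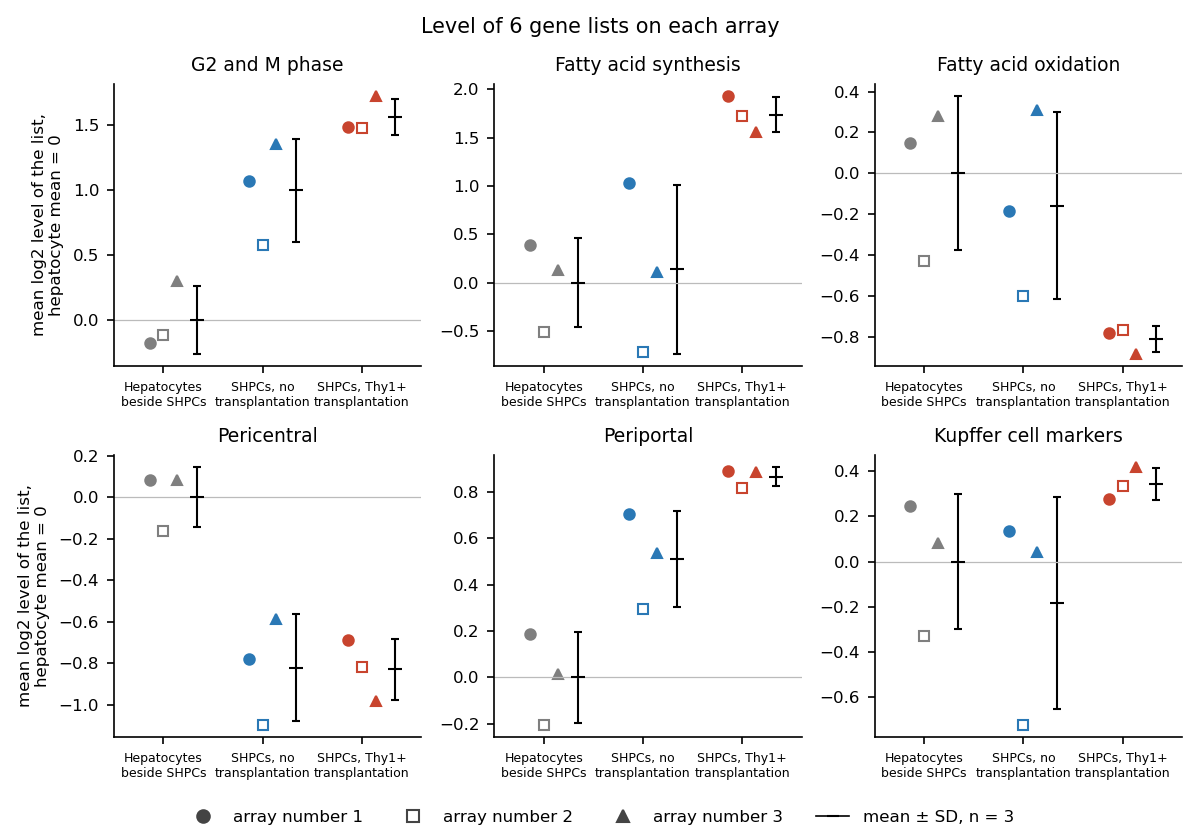
Mean log2 level of 6 gene lists on each of the 9 arrays, relative to the mean of the 3 hepatocyte arrays, which is set to 0, one panel per list. Points are arrays, and bars are group means ± SD (n = 3); the fatty acid synthesis list lies at 1.93, 1.72 and 1.56 on the transplanted group's arrays.

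The G2 and M phase list was higher in SHPCs of transplanted livers, with 20 of 22 members above and a median of 0.62 (camera adjusted p = 9.34e-10, adjusted p = 0.598 with an estimated correlation). In limma 6 members passed adjusted over the list alone, against 0 over all genes, including Kif20a, a kinesin of cell division, at 1.02 ± 0.20 (SE), Cenpf at 0.71 ± 0.14 and Ccnb1, or cyclin B1, at 0.77 ± 0.18. The S phase list did not follow, with 7 of 20 members higher and a median of −0.17 (camera adjusted p = 0.0623), and it passed with a median of −0.19 once both arrays that stood apart were left out (camera adjusted p = 8.84e-05). All 25 interferon response genes were higher, with a median of 0.56 (camera adjusted p = 9.64e-12, adjusted p = 0.598 with an estimated correlation). Of them 9 passed adjusted over the list alone, against 0 over all genes, such as Usp18 at 0.91 ± 0.17, Psmb9 at 0.91 ± 0.17 and Isg15 at 1.19 ± 0.34. The 25 Kupffer cell and macrophage markers were all higher too, with a median of 0.55 (camera adjusted p = 4.96e-10, adjusted p = 0.598 with an estimated correlation), although 0 passed adjusted over the list alone or over all genes. On SHPC array 2 the Kupffer list lay at −0.72 relative to the hepatocyte mean, against 0.13 and 0.04 for SHPC arrays 1 and 3. Leaving out SHPC array 2 took the medians of the G2 and M phase, interferon and Kupffer lists to 0.33, 0.30 and 0.20, and their camera calls were kept.

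In camera 7 further lists passed, each with at most 2 members passing adjusted over the list alone. The complement and coagulation list had a median of 0.21 (camera adjusted p = 1.65e-05, adjusted p = 0.642 with an estimated correlation), with C6 as the 1 passing member, and cyclic loess turned its median to −0.04. Urea cycle genes had a median of 0.36 (camera adjusted p = 8.61e-04, adjusted p = 0.622 with an estimated correlation), with 2 passing members, Slc25a15 and Arg1. The periportal list, of genes that hepatocytes near the portal veins express most, had a median of 0.27 (camera adjusted p = 7.06e-03, adjusted p = 0.622 with an estimated correlation), and Aldh1b1 was its 1 passing member at 1.89 ± 0.37 (SE). For the NRF2 and glutathione list the median was 0.41 (camera adjusted p = 1.13e-03, adjusted p = 0.642 with an estimated correlation), with 2 passing members, Nqo1 and Ephx1. Oxidative phosphorylation genes had a median of 0.25 (camera adjusted p = 0.0104, adjusted p = 0.789 with an estimated correlation), neutrophil and mast cell markers −0.20 (0.0120 and 0.642), and stellate cell and fibroblast markers 0.20 (0.0452 and 0.598), each with 0 passing members. None of the members of these 7 lists passed over all genes tested. Without SHPC array 2 the calls of the NRF2, oxidative phosphorylation, neutrophil and stellate lists ended, with medians of 0.11, −0.04, −0.07 and 0.08, and the complement median was 0.10. The oxidative phosphorylation call also ended without Thy1 array 1, its median was 0.40 without SHPC array 3. The stellate call also ended without SHPC array 3 or Thy1 array 2 with a median of 0.33 without SHPC array 1. The neutrophil median was −0.11 without Thy1 array 1, and the periportal call ended without both arrays that stood apart (camera adjusted p = 0.0573). After cyclic loess the medians were 0.02 for the periportal, 0.10 for the urea cycle, 0.23 for the NRF2, 0.02 for the oxidative phosphorylation and −0.08 for the neutrophil list. After renewed quantile normalization they were 0.12 for the complement, 0.11 for the oxidative phosphorylation and −0.09 for the neutrophil list, and after median centring −0.09 for the neutrophil and 0.31 for the stellate list.

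The gene for the interleukin 17 receptor B, Il17rb (probe set 17709688), is one that the study of these samples went on to examine, so its value here is no independent evidence. Its log2 level was 5.03 ± 0.72 in SHPCs and 6.41 ± 0.39 in SHPCs of transplanted livers (mean ± SD, n = 3 each), a change of 1.38 ± 0.35 (SE) with every transplanted array above every SHPC array. It did not pass over all genes tested (limma adjusted p = 0.339). In SHPCs against hepatocytes it differed by −0.06, and by 0.31 without SHPC array 2, which stood apart. Without SHPC array 2 the change of Il17rb between the SHPC groups was 1.01. Across the alternatives its adjusted p lay between 0.0221 and 0.905, and it passed with array quality weights (0.0372, change 1.12) and with the replicate number as a fixed block (0.0221) but not as a random one (0.135), numbers that do not pair these groups. Il17ra, Il17b, Il25 and Cxcr2, chosen by the same study, differed by −0.13 ± 0.13, −0.16 ± 0.16, 0.06 ± 0.19 and 0.04 ± 0.12 (limma adjusted p = 0.774, 0.780, 0.932 and 0.921). Cxcr2 was dim, at a mean of 3.12 in SHPCs with 1 array at or below its 25th percentile, so the size of its difference is uncertain. Alb, near the top of the arrays' range, differed by 0.05 ± 0.11 (limma adjusted p = 0.903), which cyclic loess turned to −0.18. The donor cell marker Thy1 differed by −0.05 ± 0.11, which median centring turned to 0.06, and Dpp4 by 0.67 ± 0.35, while Afp, the fetal liver protein, differed by 0.55 ± 0.26 (limma adjusted p = 0.904, 0.705 and 0.696). The Dpp4 and Afp differences rest in part on SHPC array 2. This shows in the other comparison that uses the SHPC mean. In SHPCs against hepatocytes Afp was at 0.04, and at −0.13 or −0.12 without SHPC array 1 or 3, which gives array 2 more weight. Without SHPC array 2 the SHPC mean of Dpp4 rose, so its difference from the same hepatocyte arrays went from −0.04 to 0.37. Although the labels call the recipients negative for its enzyme, Dpp4 RNA was at a mean linear intensity of 378 in SHPCs and 379 in hepatocytes of livers without transplantation, against array medians of 19.6 to 24.1, so its level is no measure of donor cells here. The list of interleukin 17 receptor and signalling genes, with 13 of 25 members higher, had a median of 0.04 (camera adjusted p = 0.828).

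The comparison of SHPC clusters with the hepatocytes beside them, in livers without transplantation, asks how the progenitor clusters differ from the neighbouring parenchyma. In limma 10 genes passed, 5 higher and 5 lower. Among them the cell division gene Ccnb1 was 3.00-fold and the serine dehydratase gene Sds 3.80-fold higher in SHPCs, and the glutamate transporter gene Slc1a2 was 3.74-fold lower. The spread behind these limma p-values is pooled with the transplanted group's arrays, which are not compared here and deviated less. These p-values may therefore be too small. In a fit of the compared groups alone, which has fewer arrays, 0 genes passed. As lists in camera, cell division genes and genes of the periportal zone were higher, and genes of the pericentral zone, around the central veins, and targets of p53, a protein that stops the cell cycle after DNA damage, were lower. With an estimated correlation these calls were lost (adjusted p = 0.0676 for G2 and M phase, 0.0672 for S phase, 0.107 for periportal, 0.0672 for pericentral and 0.0921 for p53 genes).

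The 5 higher genes were Fam111a at a log2 change of 1.95 ± 0.22 (SE), Sds at 1.93 ± 0.25, Ccnb1 at 1.59 ± 0.18, Amdhd1, an enzyme of histidine breakdown, at 1.53 ± 0.15, and Racgap1, a protein of cell division, at 1.14 ± 0.15. The 5 lower genes were Slc1a2 at −1.90 ± 0.25, Adam8 at −1.61 ± 0.17, the drug efflux pump gene Abcb1b at −1.56 ± 0.18, Rup2 at −1.51 ± 0.19 and Atp6v1d, a part of the proton pump of lysosomes, at −1.09 ± 0.14. Limma adjusted p-values of the 10 lay between 0.0180 and 0.0318, and for each the 3 SHPC arrays lay on one side of the 3 hepatocyte arrays. As the mean of its probe sets, Rup2 changed by −2.48. Next in each direction and not passing were Prc1, which bundles microtubules in cell division, at 1.04 ± 0.15 and Nhej1, a DNA repair gene, at −1.19 ± 0.17 (limma adjusted p = 0.0537 each, 0.0379 and 0.0189 with the fixed replicate block described next). Equal array numbers pair the SHPC and hepatocyte arrays by the check applied here. Over numbers 1 and 3 alone the correlation was only 0.0978, so this pairing rests on the number 2 arrays and is not established. With that number as a fixed replicate block 35 genes passed (23 higher, 12 lower), and as a random one 29 (15 higher, 14 lower). With the block over these groups alone, an alternative chosen after seeing the data, 147 passed (92 higher, 55 lower). All 10 genes passed in each of these fits. At an adjusted p under 0.1 there were 16 genes without the block, and at an unadjusted p under 0.05 there were 651. The count was 53 (45 higher, 8 lower) without SHPC array 2, 3 without Thy1 array 1, and 2 without hepatocyte array 1. Without SHPC array 3 it was again 10, but 2 higher and 8 lower, with 7 of the 10 genes among them. It was 0 in a fit of the compared groups alone and without SHPC array 1, Thy1 array 2 or 3, or hepatocyte array 2 or 3, and 0 after median centring or over all probe sets. The sign of each of the 10 held without any one array. Without both arrays that stood apart it was 48 (38 higher, 10 lower), of which 8 were among the 10, and Sds and Slc1a2 then missed the threshold (limma adjusted p = 0.0745 and 0.0703).

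Of the 34 lists, 14 shifted in camera, 8 higher and 6 lower in SHPCs. With an estimated correlation 0 passed (smallest adjusted p = 0.0672, with 6 lists at an unadjusted p under 0.05), and fry called 3, which were the G2 and M phase, pericentral and S phase lists. All 22 G2 and M phase genes were higher, with a median of 0.94 (camera adjusted p = 5.53e-39, adjusted p = 0.0676 with an estimated correlation). Of these 19 passed adjusted over the list alone, against 1 over all genes, including Mki67, the proliferation marker, at 2.13 ± 0.38 (SE), Top2a at 1.80 ± 0.38 and Prc1. Of 20 S phase genes 18 were higher, with a median of 0.51 (camera adjusted p = 4.44e-14, adjusted p = 0.0672 with an estimated correlation). Of these 8 passed adjusted over the list alone, against 0 over all genes, such as Mcm2 at 0.68 ± 0.16 and Mcm5 at 0.84 ± 0.21, parts of the helicase that opens DNA for copying. Mcm5 had equal values on the 3 arrays of transplanted livers, whose SD of 0 enters its SE. Of 19 p53 target genes 15 were lower, with a median of −0.38 (camera adjusted p = 1.41e-09, adjusted p = 0.0921 with an estimated correlation). Members passing adjusted over the list alone numbered 7, against 0 over all genes, including the cell cycle inhibitor gene Cdkn1a at −0.83 ± 0.13 and Ccng1 at −1.23 ± 0.26, which both passed with the block over these groups alone (limma adjusted p = 0.00847 and 0.00359). With the fixed block over all 9 arrays Ccng1 passed and Cdkn1a did not (0.0227 and 0.0620), and with the random one Cdkn1a passed and Ccng1 did not (0.0441 and 0.0969). The p53 list's median was −0.21 without SHPC array 2 and −0.58 without hepatocyte array 2, with the call kept. Kupffer cell markers were lower in these SHPCs, with 21 of 25 below and a median of −0.25 (camera adjusted p = 2.03e-03, adjusted p = 0.721 with an estimated correlation). That call ended without SHPC array 2 (median 0.02) or hepatocyte array 1 (−0.12), and the median was −0.39 without SHPC array 1, −0.38 without hepatocyte array 2 and −0.14 without both arrays that stood apart.

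Zonation genes differed on both sides. Of 11 pericentral genes 10 were lower, with a median of −0.73 (camera adjusted p = 1.81e-15, adjusted p = 0.0672 with an estimated correlation). Here 9 passed adjusted over the list alone, against 1 over all genes, including Slc1a2, the transcription factor gene Tbx3, 1.99-fold lower with an SE of 0.17 on the log2 scale, Nr1i3, a nuclear receptor that induces Cyp2b genes, at −1.66 ± 0.28, and Axin2, a target of Wnt signalling, at −0.46 ± 0.15. Of 13 periportal genes 12 were higher, with a median of 0.32 (camera adjusted p = 2.75e-09, adjusted p = 0.107 with an estimated correlation). Adjusted over the list alone 3 passed, against 1 over all genes: Sds, Aldh1b1 at 1.62 ± 0.37 and Hal, an enzyme of histidine breakdown, at 0.59 ± 0.14. Gluconeogenesis genes had a median of 0.50 with 6 of 8 higher (camera adjusted p = 1.47e-05, adjusted p = 0.275 with an estimated correlation). Of them 3 passed adjusted over the list alone, Fbp1, Got1 and Gpt, against 0 over all genes. With the fixed replicate block Aldh1b1 passed over all genes (limma adjusted p = 0.0440) and Tbx3 did not (0.0738), while with the random one Tbx3 passed (0.0484) and Aldh1b1 did not (0.166). The block over these groups alone passed both (0.00542 for Aldh1b1 and 0.00729 for Tbx3), and Fbp1 and Got1 passed in that fit only (0.0248 and 0.0288). The medians of these 3 lists without both arrays that stood apart were −0.64, 0.34 and 0.45.

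The xenobiotic P450 list was lower, with 16 of 20 members below and a median of −0.31 (camera adjusted p = 9.13e-05, adjusted p = 0.616 with an estimated correlation). Adjusted over the list alone 7 passed, against 0 over all genes, and they went both ways: Cyp1a1 at 1.53 ± 0.26 (SE) and Cyp3a2 were higher, while Cyp2b1 at −1.75 ± 0.33 and Cyp2e1 at −0.64 ± 0.18 were among the 5 lower. Cyp3a2 had a mean of 2.74 in hepatocytes, where the arrays' 25th percentiles were 2.91 to 3.08. On 2 of those arrays it lay at or below the percentile, so the size of its difference is not given. With the fixed or random replicate block Cyp1a1 passed over all genes (limma adjusted p = 0.0304 and 0.0484), and with the block over these groups alone Cyp2b1 did too (0.0212), which it did not in the others (0.0674 and 0.0956). The NRF2 and glutathione list had a median of −0.30 (camera adjusted p = 3.05e-05, adjusted p = 0.595 with an estimated correlation), with 0 members passing by either adjustment. The bile acid synthesis and transport list had a median of −0.31 (camera adjusted p = 8.37e-04, adjusted p = 0.616 with an estimated correlation), and its 2 members passing adjusted over the list alone were Abcc3 at −1.19 ± 0.23 and Amacr at −0.90 ± 0.23, with 0 over all genes. With the block over these groups alone Abcc3, Amacr and, of the NRF2 list, Gpx2 and Ephx1 passed over all genes (limma adjusted p = 0.00854, 0.0104, 0.0118 and 0.0391), and with the fixed or random block over all 9 arrays 0 of these 4 did. Without SHPC array 2 the calls of these 3 lists ended, with medians of −0.15, −0.09 and 0.01, and the bile acid call also ended without hepatocyte array 1. The NRF2 median was −0.53 without SHPC array 1, −0.52 without SHPC array 3 and −0.16 without hepatocyte array 1, and the bile acid median −0.48 without SHPC array 3, −0.18 without hepatocyte array 3 and −0.13 without both arrays that stood apart.

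For 4 lists the higher values were small. Medians were 0.17 for oxidative phosphorylation genes (camera adjusted p = 6.35e-03, adjusted p = 0.794 with an estimated correlation), 0.19 for urea cycle genes (7.46e-03 and 0.616), 0.07 for mature hepatocyte secretory and amino acid genes (0.0283 and 0.616) and 0.10 for cholangiocyte markers (0.0476 and 0.503). Adjusted over the list alone 4 of the mature hepatocyte genes passed, of which Apoa2 was lower at −1.03 ± 0.20 (SE) and Tat, Tdo2 and Hal were higher, and 0 members of the other 3 lists did, with 0 of all 4 lists over all genes. Without SHPC array 1, SHPC array 3 or hepatocyte array 2 the calls of the oxidative phosphorylation list (medians −0.0033, −0.016 and −0.12), the urea cycle list and the mature hepatocyte list ended (urea cycle 0.13, 0.16 and 0.08, mature hepatocyte 0.03, 0.07 and 0.02). The cholangiocyte call ended without SHPC array 2 (median −0.02), and it also ended without SHPC array 3 and without hepatocyte array 1 or 3. Without SHPC array 2 the oxidative phosphorylation and mature hepatocyte medians were 0.49 and 0.12, without hepatocyte array 1 the oxidative phosphorylation and urea cycle medians 0.27 and 0.32, without hepatocyte array 3 the oxidative phosphorylation median 0.33, and without hepatocyte array 2 the cholangiocyte median 0.15. With the replicate block the cholangiocyte call was lost (camera adjusted p = 0.0668), and with the block over these groups alone the mature hepatocyte call was lost as well (0.0570).

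The comparison of SHPC clusters of transplanted livers with hepatocytes of livers without transplantation shows both differences at once, since cell kind and transplantation change together. In limma 186 genes passed, 136 higher and 50 lower. Among them the cell division genes Mki67 and Ccna2, or cyclin A2, were 8.22-fold and 6.66-fold higher in these SHPCs, and Cyp2b1 and Nr1i3 were 37.6-fold and 6.14-fold lower. As lists in camera, genes of G2 and M phase, fatty acid synthesis, cholesterol synthesis, the periportal zone, the urea cycle and the interferon response were higher, and pericentral and fatty acid oxidation genes lower. With an estimated correlation 0 of these lists passed (adjusted p between 0.154 and 0.359).

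The 6 largest rises among the genes that passed were A1bg, a secreted plasma protein gene, at a log2 change of 4.11 ± 0.49 (SE), Aldh1b1 at 3.51 ± 0.37, the carbonic anhydrase gene Car3 at 3.47 ± 0.58, and Mki67 at 3.04 ± 0.38, then Rrm2, which makes building blocks of DNA, at 2.75 ± 0.46, and Ccna2 at 2.73 ± 0.37. The 6 largest falls were Cyp2b1 at −5.23 ± 0.33, Vnn1 at −3.03 ± 0.49, Cyp2b2 at −2.88 ± 0.57, Eci1 at −2.63 ± 0.31, Nr1i3 at −2.62 ± 0.28 and Cyp8b1 at −2.57 ± 0.32. Limma adjusted p-values of these 12 lay between 0.000423 and 0.0473. Il17rb was at 1.32 ± 0.35 and missed the threshold (limma adjusted p = 0.145). Calls of 29 of the 186 genes held without each array in turn, among them Cyp2b1, A1bg, Aldh1b1, Nr1i3, Cyp8b1, Eci1 and Ccnb1, and the sign of all 186 held. Other named calls held in fewer of the 9 fits that each left out 1 array. Cyp2b2 and Psmb9 passed in 2 of them, Car3, Isg15, Acacb and Insig1 in 3, and Arg1 in 1. The count was 472 without SHPC array 2, 33, 46 and 31 without Thy1 arrays 1, 2 and 3, and 49, 71 (40 higher, 31 lower) and 62 without hepatocyte arrays 1, 2 and 3. It was 575 (405 higher, 170 lower, 184 of them among the 186) without both arrays that stood apart, and 47 after median centring, 56 over all probe sets and 2685 with array quality weights.

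Of the 34 lists 19 shifted, 14 higher and 5 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.154, with 4 lists at an unadjusted p under 0.05), and fry called 3, which were the G2 and M phase, periportal and pericentral lists. All 22 G2 and M phase genes were higher, with a median of 1.66 (camera adjusted p = 4.15e-34, adjusted p = 0.154 with an estimated correlation). Over all genes 12 of them passed and adjusted over the list alone 21, led by Ccnb1 at 2.35 ± 0.18 (SE) and Cenpf at 1.48 ± 0.14. The S phase list had a median of 0.31 with 17 of 20 higher (camera adjusted p = 9.04e-05, adjusted p = 0.320 with an estimated correlation), and Rrm2 was the 1 member that passed by either adjustment. Of 19 p53 targets 13 were lower, with a median of −0.23 (camera adjusted p = 2.42e-03, adjusted p = 0.359 with an estimated correlation). Members passing adjusted over the list alone were 3, Phlda3, Cdkn1a and Plk2, against 0 over all genes. The p53 median was −0.38 without Thy1 array 1, −0.37 without hepatocyte array 2, −0.15 without hepatocyte array 3 and −0.14 after median centring. Kupffer cell markers were higher beside these lists, with 21 of 25 above and a median of 0.25 (camera adjusted p = 1.13e-03, adjusted p = 0.540 with an estimated correlation). Marco, a receptor of macrophages, was the 1 member that passed by either adjustment, at 0.80 ± 0.16, and the list's median was 0.38 without hepatocyte array 1 and 0.08 without hepatocyte array 2.

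Among lipid genes, 13 of 14 fatty acid synthesis genes were higher, with a median of 1.99 (camera adjusted p = 8.25e-14, adjusted p = 0.320 with an estimated correlation). Over all genes 3 passed, Srebf1 at 2.54 ± 0.32 (SE), Acacb at 1.65 ± 0.25 and Pnpla3 at 2.03 ± 0.38, and adjusted over the list alone 12 did. Of 17 cholesterol synthesis genes 16 were higher, with a median of 1.05 (camera adjusted p = 4.52e-12, adjusted p = 0.320 with an estimated correlation). Of them 2 passed over all genes, Insig1 at 2.34 ± 0.40 and Hsd17b7 at 1.06 ± 0.20, with 11 adjusted over the list alone. Of 20 fatty acid oxidation and PPAR alpha target genes 17 were lower, with a median of −0.64 (camera adjusted p = 2.66e-09, adjusted p = 0.359 with an estimated correlation). Over all genes 3 passed, Cpt1a at −1.69 ± 0.23, Vnn1 and Cyp4a1 at −1.39 ± 0.26, and adjusted over the list alone 5 did. Interferon response genes were all higher, 25 of 25, with a median of 0.50 (camera adjusted p = 4.89e-09, adjusted p = 0.359 with an estimated correlation). Isg15 at 2.00 ± 0.34 and Psmb9 at 0.87 ± 0.17 passed over all genes, with 8 adjusted over the list alone. Hepatocyte array 2, one of the arrays that stood apart, held the fatty acid synthesis list at −0.51, and without both such arrays the medians of these 4 lists were 1.72, 0.91, −0.81 and 0.40.

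Of 13 periportal genes 11 were higher, with a median of 0.65 (camera adjusted p = 2.66e-09, adjusted p = 0.179 with an estimated correlation). Over all genes 4 passed, Sds at 2.58 ± 0.25 (SE), Aldh1b1 at 3.51 ± 0.37, Arg1 at 0.68 ± 0.13 and Hal at 0.71 ± 0.14, and adjusted over the list alone 9 did. All 11 pericentral genes were lower, with a median of −0.65 (camera adjusted p = 2.66e-09, adjusted p = 0.154 with an estimated correlation). Here 4 passed over all genes, Slc1a2 at −2.31 ± 0.25, Nr1i3 at −2.62 ± 0.28, Ahr at −1.13 ± 0.21 and Tbx3 at −0.90 ± 0.17, with 6 adjusted over the list alone. All 8 urea cycle genes were higher, with a median of 0.62 (camera adjusted p = 2.49e-06, adjusted p = 0.359 with an estimated correlation). Cps1, Ass1, Asl and Arg1 belong to the periportal list as well, so the calls of these lists are not separate. Slc25a15 at 1.03 ± 0.16 and Arg1 passed over all genes and 6 adjusted over the list alone. Gluconeogenesis genes had a median of 0.48 (camera adjusted p = 4.95e-04, adjusted p = 0.359 with an estimated correlation), with Got1 at 1.27 ± 0.15 as the 1 member passing over all genes and 4 adjusted over the list alone, and a median of 0.30 without hepatocyte array 2.

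Of the other lists that shifted, oxidative phosphorylation genes had a median of 0.47 (camera adjusted p = 4.36e-06, adjusted p = 0.536 with an estimated correlation) with 0 members passing, and 0.21 without hepatocyte array 2. The unfolded protein response and chaperone list had a median of 0.26 (7.68e-03 and 0.401); adjusted over the list alone 9 passed, 6 higher, such as Pdia6 and Calr, and 3 lower, Trib3, Hsph1 and Hspb1, with 1 over all genes. Mature hepatocyte genes had a median of 0.21 (2.42e-03 and 0.388), with 2 passing over all genes, Tdo2 and Hal, and 6 adjusted over the list alone. Complement and coagulation genes and acute phase genes both had medians of 0.19 (5.23e-04 and 0.536, 2.30e-03 and 0.401), C6 and A2m were their 1 member each passing over all genes, and 2 of each list passed adjusted over the list alone. Cyclic loess turned both medians to −0.01, and the complement median was 0.12 without Thy1 array 3. The xenobiotic P450 list had a median of −0.21 (2.30e-03 and 0.538), with 2 lower over all genes, Cyp2b1 and Cyp2b2, and 6 adjusted over the list alone, of which Cyp2c22 was higher. That call ended without hepatocyte array 3 (median −0.14), and the median was −0.40 without hepatocyte array 2 and −0.12 after median centring. Neutrophil and mast cell markers had a median of −0.19 (0.0177 and 0.463) with 0 members passing, −0.10 after median centring, and the call ended without hepatocyte array 2 (median −0.03). Cyclic loess gave medians of 0.08 for the mature hepatocyte, 0.12 for the unfolded protein response, 0.30 for the oxidative phosphorylation, 0.29 for the gluconeogenesis and 0.15 for the Kupffer list, and renewed quantile normalization 0.14 for the unfolded protein response and 0.11 for each of the complement and acute phase lists.

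Genes shared by both SHPC groups against hepatocytes were the same 10 that passed in SHPCs of livers without transplantation: Fam111a, Sds, Ccnb1, Amdhd1 and Racgap1, higher in both, and Slc1a2, Adam8, Abcb1b, Rup2 and Atp6v1d, lower in both. Independent lists of the same sizes would share 0.0431 higher and 0.0158 lower genes. Because both comparisons use the same 3 hepatocyte arrays, 100 simulated pairs of comparisons were drawn, with a median of 0 shared genes. Each pair set unchanged groups against a shared hepatocyte group that was simulated too, so the real hepatocyte arrays are not in the draws. Every simulated array mixed the deviations of all real arrays. By design, no simulated group therefore held a single array that stood apart or had a spread unlike the others. Of these draws 2 shared 10 or more, with 35 and 2091 genes, which set the averages of 16.6 higher and 4.67 lower. The covariance of the log2 changes over genes was 0.0428, against 0.0259 on average and 0.0890 at the 95th percentile in the simulated pairs, a difference of 0.0169 from the average. With 3 hepatocyte arrays the controls could not be split, so part of the overlap may come from them. The overlap was 48 without SHPC array 2, 1 without Thy1 array 1 or hepatocyte array 1, and 0 without SHPC array 1, Thy1 array 2 or 3, or hepatocyte array 2 or 3; it was 40 without both arrays that stood apart and 32 with the replicate block.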

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

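Leaving out both SHPC array 2 and hepatocyte array 2, and the replicate block over SHPC and hepatocyte arrays only, were chosen after seeing the data. Counts of changed genes are given here for SHPCs with against without transplantation, SHPCs against hepatocytes, and SHPCs of transplanted livers against hepatocytes, in that order, beside 1, 10 and 186; the cause of the moves was not tested. They were 17, 17 and 328 after renewed quantile normalization, 0, 0 and 47 after median centring, 40, 34 and 440 after cyclic loess, 0, 0 and 56 over all probe sets, and 259, 375 and 2685 with array quality weights. A fit of the compared groups alone gave 0, 0 and 304, and leaving out both arrays 23, 48 and 575. An adjusted p under 0.1 gave 9, 16 and 303, and an unadjusted p under 0.05 with a 2-fold change 131, 83 and 294. Without each array in turn they lay at 0 to 24, 0 to 53 and 31 to 472. Counts stayed within 1.5 times under both other dim filters, the mean of probe sets, the trend and robust settings, and the adjusted p with a 2-fold change. With the replicate number as a fixed replicate block they were 64, 35 and 367, and as a random one 10, 29 and 305; the block over SHPC and hepatocyte arrays gave 147 for that comparison. Same-numbered Thy1 arrays did not deviate together with SHPC arrays (correlations 0.00234, −0.0936 and −0.0390) or hepatocyte arrays (−0.0690, −0.0797 and −0.0904), and no Thy1 array correlated best with its own number, so those blocks pair nothing. Apart from the calls given beside the SHPC and hepatocyte results, the block changed no call of those groups' named genes or lists from passing to not passing.

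Counts of shifted lists, beside 13, 14 and 19, were 0, 0 and 0 with an estimated correlation and 0, 3 and 3 with fry. Without each array they were 11 to 15, 11 to 14 and 19 to 22, and they stayed within 1.5 times on ranks, without the dim filter, after median centring, with the block and without both arrays (10, 19 and 21). Oxidative phosphorylation genes changed sign between the SHPC groups without SHPC array 2 (−0.035; range without each array −0.035 to 0.40), also without both arrays (−0.035), and between SHPCs and hepatocytes without SHPC array 1 (−0.0033), SHPC array 3 (−0.016) or hepatocyte array 2 (range −0.12 to 0.49). There Kupffer markers (range −0.39 to 0.024), bile acid genes (0.013) and cholangiocyte markers (−0.017) changed sign without SHPC array 2. Genes shared by both SHPC groups against hepatocytes, beside 10, numbered 32 with the block, 40 without both arrays, 16 at an adjusted p under 0.1 and 0 to 48 without each array. Of 2632 values of named genes under an alternative, 166 newly passed, 223 no longer did, and 35 values of 7 genes, which did not pass there, changed sign. Of 750 list values 620 still passed in the same direction, and the 8 that changed sign are those just given, cyclic loess not being among those settings. Signal over background was not analysed here, so what dimness limits is open.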

Other observations

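The tests of whole livers, of portal tracts, of other cells in SHPCs of livers without transplantation and of regroupings by pairs were chosen after the results they measure had been seen. Fetal and progenitor hepatocyte genes, such as Epcam, did not pass as a list: their medians were 0.11 between the SHPC groups, 0.06 in SHPCs against hepatocytes and 0.31 in SHPCs of transplanted livers against hepatocytes (camera adjusted p = 0.435, 0.108 and 0.0593). In the last comparison Prom1 at 1.21 ± 0.25 (SE), Epcam at 0.89 ± 0.28 and Foxm1 at 0.44 ± 0.12 passed adjusted over the list alone, against 0 over all genes. Foxm1 had equal values on the 3 SHPC arrays without transplantation, whose SD of 0 enters its SE. Bile acid genes had no common direction between the SHPC groups (median 0.41, camera adjusted p = 0.379). There Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.82 ± 0.51 was higher and Cyp8b1 at −2.26 ± 0.32 and Abcb4 at −0.61 ± 0.17 lower in transplanted livers, adjusted over the list alone, with 0 over all genes. In SHPCs of transplanted livers against hepatocytes the bile acid list had a median of −0.11 (0.203), with Cyp8b1 and Amacr lower over all genes. A2m, an acute phase protein in rats, was at 2.03 ± 0.35 in SHPCs against hepatocytes and passed adjusted over the list alone, while the list did not (median 0.02, camera adjusted p = 0.108). Between the SHPC groups the acute phase list had a median of 0.18 (0.0626), which cyclic loess turned to −0.04.

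Among growth genes, Fgf1 at 0.78 ± 0.15 (SE) passed over all genes in SHPCs of transplanted livers against hepatocytes and Hgf at −0.77 ± 0.19 adjusted over the list alone, with list medians of 0.05, 0.01 and 0.05 in the same order of comparisons (camera adjusted p = 0.914, 0.593 and 0.658). Tfrc, the transferrin receptor gene, passed there too at 1.18 ± 0.23, while the erythroid list, with medians of 0.01, 0.09 and −0.06, did not (0.556, 0.217 and 0.916). Medians were 0.01, −0.05 and −0.01 for Hippo YAP targets (0.825, 0.428 and 0.745), 0.03, 0.02 and 0.02 for glycolysis genes (0.973, 0.983 and 0.956), and 0.15, 0.01 and 0.12 for ribosomal protein genes (0.0766, 0.984 and 0.0616). For the interleukin 17 list they were −0.10 and −0.06 in the hepatocyte comparisons (0.539 and 0.907). Endothelial markers had 0.14, −0.10 and 0.10 (0.166, 0.30 and 0.662), T and NK cell markers −0.05, 0.03 and 0.07 (0.594, 0.145 and 0.543), B cell markers −0.07, 0.08 and −0.10 (0.222, 0.593 and 0.510), and mesothelial markers 0.01, −0.07 and −0.08 (0.828, 0.942 and 0.922). Median, mean and camera direction differed in sign for the erythroid, T and NK, mesothelial and glycolysis lists between the SHPC groups, for the complement, mesothelial, glycolysis, ribosomal and neutrophil lists in SHPCs against hepatocytes, and for the interleukin 17, erythroid and mesothelial lists in the last comparison.

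Fatty acid oxidation genes were lower in SHPCs of transplanted livers than in other SHPCs in camera at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.598) and in fry (adjusted p = 0.307). Camera called 13 lists here and a median of 8 (95th percentile 18.1) in draws of unchanged groups. The draws counted called lists only, so they do not decide on this one. As its call was lost in both other tests, whether the list shifted at all is open. Without both arrays that stood apart the list kept 180% of its median, which argues against those arrays as the whole cause. Another time of day at tissue collection may be involved and stays open: 0 of 6 clock genes tested differed by the predicted amount, but the intervals for Nr1d1 (0.62, 95% confidence interval −0.12 to 1.35) and Bmal1 (0.57, 0.11 to 1.03) allow it. The change could also be one of whole livers, as no hepatocytes of transplanted livers were analysed here (the list's median was −0.067 in SHPCs against hepatocytes without transplantation), and one brought by the Thy1+ cells is untested.

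G2 and M phase genes were higher in SHPCs of either kind than in hepatocytes in camera and in fry (fry adjusted p = 0.0436 and 0.00860), but not with an estimated correlation (adjusted p = 0.0676 and 0.154). Camera called 14 and 19 lists there against medians of 9.5 and 7 (95th percentile 18 and 17.1, maximum 21 and 20) in unchanged draws. Without both arrays that stood apart the G2 and M phase list kept at least 91.8% of its median, which argues against those arrays as the cause. Dividing non-parenchymal cells inside the clusters stay open in SHPCs without transplantation, where the highest of 4 marker list medians was 0.034 for T and NK cells. The markers, at list medians of 4.55 to 7.23 in hepatocytes against 4.48 for G2 and M phase genes, could hide a small share of such cells. Intensities of different probe sets do not compare directly, so these levels do not decide it. In SHPCs of transplanted livers they might contribute too, since the Kupffer list had a median of 0.25, with Marco, Clec4f and C1qa at 9.26, 8.50 and 8.26 against 8.45, 8.44 and 8.49 in hepatocytes (log2 intensity), and 1 of that list's genes is held by another list. The cell kind itself, SHPC against hepatocyte, stays an open explanation.

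Pericentral genes were lower in SHPCs of transplanted livers than in hepatocytes in camera and in fry (fry adjusted p = 0.0109), but not with an estimated correlation (adjusted p = 0.154). The 19 lists called there stand against a median of 7, a 95th percentile of 17.1 and a maximum of 20 in unchanged draws. Without both arrays that stood apart the pericentral list kept 101% of its median, which argues against those arrays as the cause. Captured regions nearer to portal tracts are a candidate explanation, as the periportal list was higher by a median of 0.65. A periportal programme of the SHPCs themselves would give the same values and stays open.

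As a hypothesis, transplantation could move SHPCs further along the difference between SHPCs and hepatocytes. The covariance over genes of both changes was −0.00880, against a mean of −0.0281 and a 95th percentile of 0.0211 in simulated unchanged groups, so the test did not decide. The bound set for rejecting it, a value at or below that percentile, was wrong, since missing a 95th percentile excludes nothing.

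The 6 arrays of each comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. Between the SHPC groups the real split gave 1 gene and 13 lists, the highest other split 0 and 15, and 4 splits had as many lists. In SHPCs against hepatocytes the real split gave 10 genes and 14 lists, with 2 splits at as many genes and 4 at as many lists. The highest other there, 10 genes and 20 lists, set SHPC arrays 1 and 3 and hepatocyte array 1 against the rest, which puts both arrays that stood apart on one side. It parts 1 of the 3 pairs of equal number, while the real split parts all 3, and the other splits that do so gave 0 genes and at most 8 lists. In SHPCs of transplanted livers against hepatocytes the real split gave 186 genes and 19 lists, the highest other 0 and 13, and 1 split, the real one, had as many of either. For the 10 shared genes, 4 of 100 regroupings of the 9 arrays, the real one included, gave as many and the highest other 14. These regroupings disregard the pairs of equal number; among the 46 that part all 3 pairs, as the real groups do, 1, the real one, gave as many and the highest other 1. Unchanged groups against a shared simulated hepatocyte group shared 10 or more genes in 2 of 100 draws. These shares lie under 0.05, but they do not exclude chance for that count. Regroupings treat arrays as independent, although the number of animals was not given, and the pairs rest on the number 2 arrays. The count ranged from 0 to 48 without each array in turn, and was 0 or 1 without most of them. Part of the overlap may still come from the shared hepatocyte arrays.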
